A study of Mus musculus with 3 samples.

How the data were processed

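Plasma miRNA was measured on 3 single-colour microarrays, 1 for each group of male C57BL/6 mice aged 8 weeks: caged controls, mice after aerobic exercise and mice after resistance exercise. C57BL/6 is a common inbred laboratory strain. Per the labels' protocols, plasma from 3 mice of a group, 100 µl each, was combined into 1 pool of 300 µl, so each array stands for 1 pool. Blood was drawn from the inferior vena cava 3 h after a single bout of exercise in animals fasted overnight. Plasma was spun at 3000 g and again at 16000 g, each for 10 min, the latter to clear debris, per the labels. RNA was extracted with a miRNeasy kit and labelled with Cy5 (also given as Hy5), per the labels. The extraction text speaks of cells as the source of the RNA, while the other labels name plasma, and plasma was taken as the source here. The exercise regimens, the scanner and the scanning software with its version are not given in the sources used here. The series text names the chip as a human one, while all 1900 miRNA probes in the deposited files carry mouse names, and the mouse names were used. How the chip's other spots were designed is not given in the sources used here.

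The deposited scanner files hold the raw intensity of 3200 spots per array on a linear scale, per the file headers. Each miRNA probe has 1 spot, and 12 probes name more than 1 miRNA. The files also hold the authors' background-subtracted intensity and their globally normalized intensity. From the values, the authors subtracted 1 background intensity per array and left spots near background empty. They then multiplied by 1 factor per array so that the median miRNA with a value stood at 25. The authors' value table of the whole series repeats that normalized intensity to within 0.05 with the same empty cells. Its scale is therefore linear, its columns each have a median of 25, and it is not centred per miRNA.

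The background of each array was the mean of its 896 blank spots after trimming 5% at each end, which left 806 spots. A miRNA counted as detected where its raw intensity lay above that mean by more than 2 SD of the trimmed blanks. The rounding of the trim was chosen after the files had been seen because it gave 0 differences from the authors' own empty cells on every array. Raw intensities were background corrected with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50 and that blank mean as background. Control spots were then left out and the 1900 miRNA probes were quantile normalized over the 3 arrays on the log2 scale. Differences are given as normalized log2 intensities of 1 pool minus another, or as the fold of the brighter over the dimmer pool. The offset pulls folds of dim miRNAs towards 1. For the largest differences of each comparison, where the fold in the authors' table was over 1.5 times larger, the table's value is given too.

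Each group has 1 array, so the design has no replicates, no test was run and no p-value is given. Counts are of miRNAs detected on both arrays whose log2 intensities differed by 1 or more. A miRNA detected on only 1 of 2 arrays has a lower bound on its fold, the brighter value over the higher of the dim array's detection floor and the dim spot's own value. The only measure of error is technical: repeated spots of 2 spike-in probes had a pooled SD of 0.11 on the log2 scale. For a difference between 2 single spots this gives 0.16, and 2 SD of it 0.32, the limit meant by 2 SD of spot scatter. The spike spots were preferred to the S-Probe spots, with a pooled SD of 0.07, after both had been seen. The spikes are far brighter than most miRNAs, however, and most S-Probe spots lay at background. The dim S-Probe7 had an SD of 0.20 on the control array and 0.15 and 0.14 on the aerobic and resistance arrays. The 16 spots of Negative Control 1, dimmer still, had SDs of 0.29, 0.33 and 0.28 in the same order, and their pooled SD of 0.30 gives 0.85 for 2 SD of a difference. The limit of 0.32 may thus be too narrow for dim miRNAs. Neither covers differences between mice, pools or array hybridizations. For arrays, their number limits the precision.

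The processing was tested on simulated data, with 3 arrays drawn from the mean signals over all 1900 miRNAs, spot scatter and blank noise, and 200 miRNAs with a signal over 20 altered in the simulated aerobic array. All compared miRNAs altered in either direction had the right sign in the comparison of the aerobic with the control array. At the offset of 50, however, just 2% of those simulated at 2-fold higher and 78% of those at 4-fold higher reached 2-fold. In the lower direction the shares were 6% for a fold of 0.5 and 38.6% for a fold of 0.25. Of simulated unaltered miRNAs, 0.0922% reached 2-fold in that comparison. Altered miRNAs can thus miss the 2-fold mark at this setting, and folds of dim miRNAs are compressed. The simulated noise was spot scatter and blank noise alone, so unaltered miRNAs on real arrays may reach 2-fold more often. With an offset of 0 the shares were 14% and 94% higher and 40% and 97.7% lower.

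Before the data were examined, 15 miRNA lists were fixed, for skeletal and cardiac muscle, erythrocyte, platelet, leukocyte, liver, endothelium and smooth muscle, brain and neuron, epithelium with gut and pancreas, adipose and metabolic, hypoxia and inflammation, bone and cartilage, and the let-7, miR-30 and miR-29 families and the miR-17-92 cluster with its paralogues. Of their 134 miRNA names counted over all lists, 132 were on the array, and miR-197-3p and miR-885-5p were not. A list's median difference was set against the medians of 10000 random lists of the same size matched on mean intensity in 20 bins. The resulting percentile describes these arrays and is no p-value. A second percentile, against random lists of low-numbered miRNAs of like intensity (the let-7 family and names below 500, each member drawn from its 20 nearest), was added after the list values had been seen. Several lists share members, and probes of near-identical miRNAs, such as those of the let-7 family, miR-133a-3p with miR-133b-3p and miR-23a-3p with miR-23b-3p, may hybridize with each other's targets. Members of random lists were drawn separately, so a list whose members move together reaches an extreme percentile more easily.

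The miRNAs named were chosen by a rule fixed before the data were examined. It takes the 10 largest positive and 10 largest negative differences of each exercise pool from control among miRNAs detected on both arrays. It adds the 3 largest bounds each way, the 5 largest differences each way between the exercise pools, all list members and the 3 brightest miRNAs of each array. Other miRNAs are marked as chosen after their values were seen. Correlations between the differences from control, and the miRNAs they share, were set beside 100 simulations of unaltered groups that share the control array. The scatter of these simulations was about as wide as that of the observed differences, so it may hold real differences too.

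The alternatives fixed beforehand were subtraction of the blank mean, an offset of 0, scaling to the median, scaling to the 75th percentile, no scaling, the authors' table, detection at 10 SD and no detection filter. Another 4 were added after the data had been seen: detection above the 95th percentile of the array's spots without a probe, 1 common detection distance on all arrays, a 1.5-fold threshold, and the authors' table with detection at 10 SD. Gene neighbourhoods were read from RefSeq genes of GRCm38.p6, and no coordinates are printed because the sources used here name no build. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest. Control spots were left out of all comparisons of miRNAs.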

Results

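Circulating miRNAs were profiled in mouse plasma to compare a single bout of aerobic exercise, a single bout of resistance exercise and normal caging. miRNAs are short RNAs that repress messenger RNAs, and those in plasma come from blood cells, vessel walls and other tissues. Each of the 3 groups was represented by 1 pool of plasma from 3 mice on 1 array, so there were no replicates. No difference below has an error that covers mice or arrays.

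The brightest miRNAs were the same on all 3 arrays. They were miR-2861 and miR-3960, neighbours described in osteoblast differentiation, and miR-5126, for which no function is given here. Together these 3 carried 26.5% of the signal above background in the control pool, 26.5% in the aerobic pool and 27.6% in the resistance pool. The raw intensity of miR-2861 was 47010 in control, 51339 in aerobic and 42078 in resistance plasma. Red cell miR-451a was also bright, at 3056, 5741 and 5245 in the same order. The spot of muscle-enriched miR-133a-3p was far dimmer, at 325.5 in the control pool against a blank mean of 92.01. Intensities of different probes depend on the probe as well, so their order need not be that of amounts in plasma. The heart miRNAs miR-208a-3p, miR-208b-3p and miR-499-5p were not detected on any array.

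Of 1900 miRNA probes, 1431 (75.3%) were detected in control, 1364 (71.8%) in aerobic and 1372 (72.2%) in resistance plasma. All arrays detected 1296 of them, and 401 were detected on none. Many sat near background. At a threshold of 10 SD the counts were 990, 808 and 886. On the control array 78.7% of the printed spots without a probe also passed the detection threshold, against 4.02% on the aerobic and 20.1% on the resistance array. With 1 common detection distance on all arrays the counts were 1242, 1364 and 1237, and the control array no longer had the most. Spike-in spots, before scaling, were brighter than control by 0.13 (log2) for both probes on the aerobic array and by 0.05 and 0.04 on the resistance array.

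The first comparison was of aerobic exercise with control. Muscle miRNAs were the group that stood lowest after aerobic exercise. miR-133a-3p and miR-133b-3p, which are enriched in skeletal and cardiac muscle, were 2.93-fold and 2.79-fold lower in the aerobic pool. miR-1a-3p, their partner in muscle differentiation, was 1.99-fold lower. The largest difference of all was miR-6912-5p, 3.37-fold lower. Blood cell miR-16-5p, liver miR-122-5p and the let-7 family, which restrains growth and proliferation genes, were higher in aerobic plasma by less than 2-fold.

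In log2 terms miR-133a-3p stood at -1.55, miR-133b-3p at -1.48 and miR-1a-3p at -0.99 against control. In the authors' table the folds of the same miRNAs were larger, at 5.24, 4.51 and 8.25. The last of these rests on a spot of raw intensity 104.1 on the aerobic array, which lay under the 10 SD threshold there. Of the 8 probes on the muscle list 4 were detected on both arrays, and 3 of those were lower by more than 2 SD of spot scatter. The fourth, a probe shared by miR-486a-5p and miR-486b-5p, which red cells also carry in quantity, was higher by 0.26. The median of the muscle list was -1.24, below every one of the 10000 random lists, whether drawn from all or from low-numbered miRNAs. It was -2.31 with the blank mean subtracted and -0.14 over all 8 probes without a detection filter. miR-206-3p, a skeletal muscle miRNA, was near background and not detected on the aerobic array. Its bound of 1.10-fold lower lay within spot scatter.

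Lower miRNAs outside the muscle list mostly carried numbers of 1000 or higher, as did 831 of all 1321 miRNAs compared. No function is given for them here. miR-6912-5p stood at -1.75 and the other arm of its hairpin, miR-6912-3p, at -0.68. miR-3093-5p was lower by a log2 difference of -0.77, miR-7666-3p of -0.69, miR-6918-5p of -0.62, miR-5123 of -0.61 and miR-5129-5p of -0.57. In the authors' table miR-5123 was 3.19-fold lower, against 1.52-fold here, and miR-6912-3p stood at a log2 difference of -1.32.

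Among the higher miRNAs, miR-212-3p, which is induced by neuronal and hormonal signals, led with 0.89. Its other arm, miR-212-5p, chosen after its value was seen, stood at 0.15. The start of Mir132 lies 294 bp from that of Mir212. miR-132-3p was near background, at raw intensities of 96.4 in control and 93.6 in aerobic plasma, where it was not detected. miR-16-5p followed with 0.82, miR-6239 with 0.75, miR-122-5p, the dominant miRNA of hepatocytes, with 0.68 and miR-5100 with 0.66. Then came miR-1982-5p (0.61), miR-8110 (0.54), let-7a-5p (0.51), miR-1224-5p (0.49) and miR-760-3p (0.46). All 10 exceeded 2 SD of the spike spots' scatter, but they were picked as the largest of 1321 differences. Of all these differences 94.2% lay within that limit. Only miR-212-3p exceeded the 0.85 given by the Negative Control 1 spots.

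The erythrocyte list and 3 family lists had medians above control. All 8 compared erythrocyte probes were higher, 5 by more than 2 SD of spot scatter, with a list median of 0.35. Its members miR-451a and miR-144-3p, which share a hairpin cluster needed for red cell formation, were higher by 0.35 and 0.40. All 10 let-7 probes were higher, 6 by more than 2 SD, with a median of 0.38, and 12 of 13 probes of the miR-17-92 group, which promotes proliferation, 6 by more than 2 SD, with a median of 0.28. The miR-30 family, broadly expressed and abundant in heart, had a median of 0.27 with 5 of 5 probes higher, 2 by more than 2 SD. The percentiles of these 4 lists among random lists were 100, 100, 100 and 97.54. Against low-numbered miRNAs alone they were 99.9, 100, 100 and 72.8, so the miR-30 family did not stand apart from other low-numbered miRNAs.

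The liver list had a median of 0.20 with 5 of 5 probes higher, at the 99.9th percentile of all lists and the 100th of low-numbered ones. Without miR-122-5p its members differed from control by at most 0.21. The platelet list (median 0.25) and the endothelium and smooth muscle list (0.18) lay at the 99.2th and 98.7th percentiles, but at 83.7 and 62.3 among low-numbered miRNAs. Of the 8 platelet probes 1 was higher by more than 2 SD, and of the 7 leukocyte probes 0. The adipose list (0.10) lay at 99.5 and 97.2 and the leukocyte list (0.13) at 98.7 and 82.3. The miR-29 family (0.12) lay at 90.1 and 54.6. The brain list (0.05), the bone and cartilage list (0.04), the hypoxia list (0.01) and the epithelium list (0.00) lay between the 53.7th and 88.3th percentiles, and at 84.9, 49.8, 12.2 and 52.4 among low-numbered miRNAs. The sign of each of these 4 medians flipped under at least 1 alternative.

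Of 1321 miRNAs compared, 0 were at least 2-fold higher and 3 at least 2-fold lower in the aerobic pool, namely miR-6912-5p, miR-133a-3p and miR-133b-3p. The count depended on the processing: an offset of 0 gave 2 higher and 9 lower, the authors' table, which is also scaled in another way, 18 and 12, and blank subtraction 6 and 29. All 3 lower miRNAs remained among the lower ones in each case. In simulated arrays 2% of miRNAs made 2-fold higher and 78% of those made 4-fold higher reached the 2-fold mark at this setting, so a count of 0 does not exclude 2-fold differences. Only detected on 1 of the 2 arrays were 43 miRNAs in the aerobic pool and 110 in control. The largest bounds were 1.12-fold higher for miR-6350, 1.12-fold for miR-195b and 1.11-fold for miR-148b-3p, and 1.19-fold lower for miR-6920-5p. All of these lay within spot scatter, and 64 of the 110 miRNAs of the control pool had a bound over 1. Such bounds leave larger differences open.

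**Figure D1:**
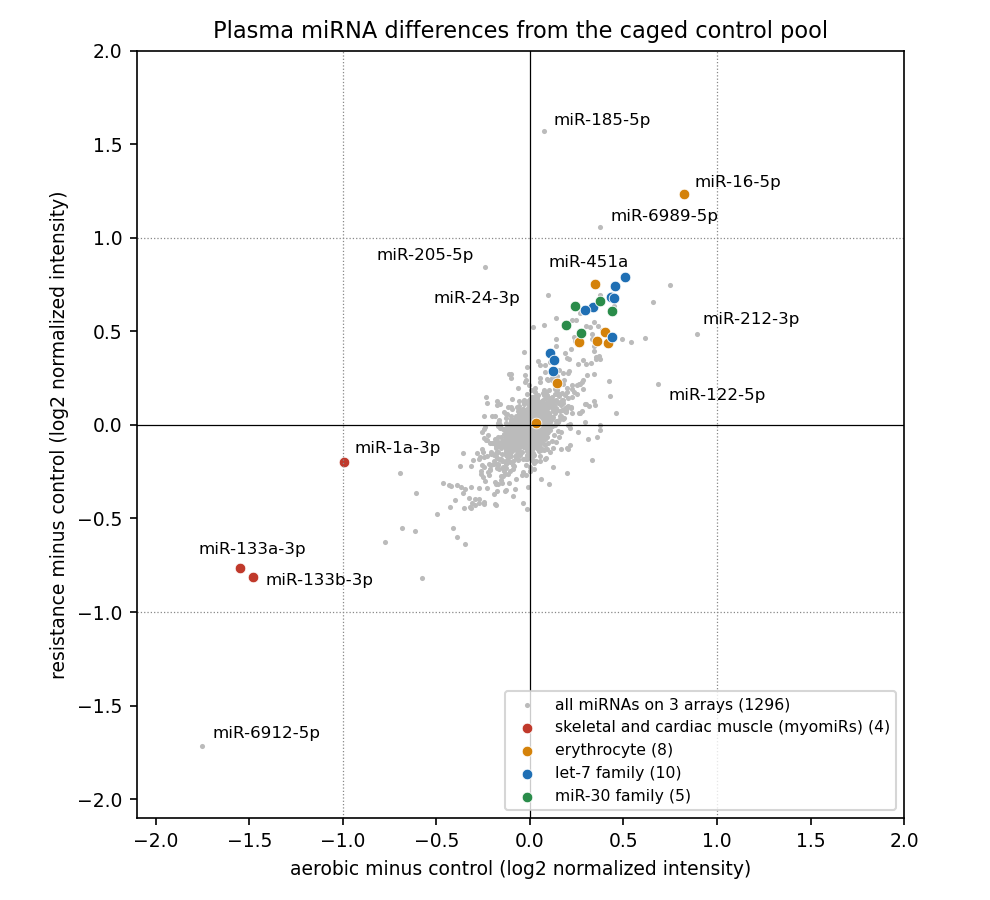
Each point is 1 of the 1296 miRNAs detected on all arrays, with its aerobic minus control difference on the x axis and its resistance minus control difference on the y axis, both in log2 normalized intensity, 1 array per pool. Dotted lines mark 2-fold, colours mark 4 of the fixed lists (the probe of miR-486a-5p and miR-486b-5p belongs to both the muscle and the erythrocyte list and is drawn in the erythrocyte colour), and miR-133a-3p, at -1.55 and -0.77, lies lower left while let-7a-5p, at 0.51 and 0.79, lies upper right.

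The next comparison was of resistance exercise with control. miR-185-5p was 2.97-fold higher in resistance plasma, red cell miR-16-5p 2.36-fold and miR-6989-5p 2.08-fold. Epithelial miR-205-5p and red cell miR-451a were 1.80-fold and 1.68-fold higher. The let-7 and miR-30 families were higher as groups. miR-6912-5p was 3.29-fold lower. The muscle miRNAs miR-133a-3p and miR-133b-3p were 1.70-fold and 1.76-fold lower, while miR-1a-3p differed by no more than spot scatter.

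miR-185-5p stood at 1.57 (log2), with raw intensities of 106.3 in control, 116.9 in aerobic and 243.2 in resistance plasma. Because its control spot was dim, the authors' table gave a fold of 9.87. miR-16-5p stood at 1.24, miR-6989-5p at 1.06, miR-205-5p at 0.85, let-7a-5p at 0.79, miR-451a and miR-6239 each at 0.75, and let-7d-5p at 0.74. miR-126a-5p, from the endothelial miR-126 hairpin, and miR-26a-5p each stood at 0.70. On the lower side miR-6912-5p stood at -1.72 and miR-6912-3p at -0.55. miR-5129-5p stood at -0.82, miR-7221-3p at -0.63, miR-3093-5p at -0.63, miR-762 at -0.60, miR-6918-5p at -0.56 and miR-7238-5p at -0.55.

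On the muscle list, miR-133b-3p stood at -0.81, miR-133a-3p at -0.77, miR-1a-3p at -0.20 and miR-206-3p at -0.06, and the shared miR-486 probe was higher by 0.44. The list median of -0.20 lay at percentile 1.40 of all random lists and 0.03 of low-numbered ones. It became -0.57 in the authors' table and -0.01, at percentile 44.3, without a detection filter, which adds the 3 heart probes detected on no array.

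Of all 1336 miRNAs compared, 91.2% lay within 2 SD of spot scatter. All 10 let-7 probes were higher, 9 by more than 2 SD of spot scatter, with a median of 0.62. All 5 miR-30 probes were higher by more than 2 SD, with a median of 0.61 and a range from 0.49 for miR-30e-5p to 0.66 for miR-30d-5p. All 8 erythrocyte probes and all 14 probes of the miR-17-92 group were higher, 6 of 8 and 7 of 14 by more than 2 SD, with medians of 0.45 and 0.32. These 4 lists lay at percentiles 100, 99.9, 100 and 100, and among low-numbered miRNAs at 100, 97.3, 97.1 and 99.8. The platelet list had a median of 0.39, with 7 of 8 probes higher, 6 by more than 2 SD, among them miR-24-3p at 0.69 and miR-21a-5p at 0.60, and myeloid miR-223-3p was its 1 lower member at -0.06. The endothelium and smooth muscle list had a median of 0.33 with 7 of 7 probes higher. Their percentiles of 99.9 and 99.7 dropped to 83.7 and 82.3 among low-numbered miRNAs.

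The adipose list had a median of 0.22, at percentiles 100 and 99.4 of the same kinds of random list, with miR-378a-3p, encoded in the gene for the metabolic coactivator PGC-1beta, at 0.52. The hypoxia and inflammation list had a median of 0.19, at 99.6 and 76.7, although miR-210-3p, the classical hypoxia miRNA, differed by 0.00. The liver list (0.14) lay at 99.3 and 88.9, the leukocyte list (0.13, with 1 of 7 probes higher by more than 2 SD) at 98.6 and 67.5, the epithelium list (0.08) at 99.7 and 98.3 and the miR-29 family (0.21) at 91.1 and 53.5. The brain list stood at -0.06 and percentiles 8.61 and 2.35. The bone and cartilage list stood at 0.00 and percentiles 68.0 and 15.2, with a sign that depended on the alternative.

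**Figure D2:**
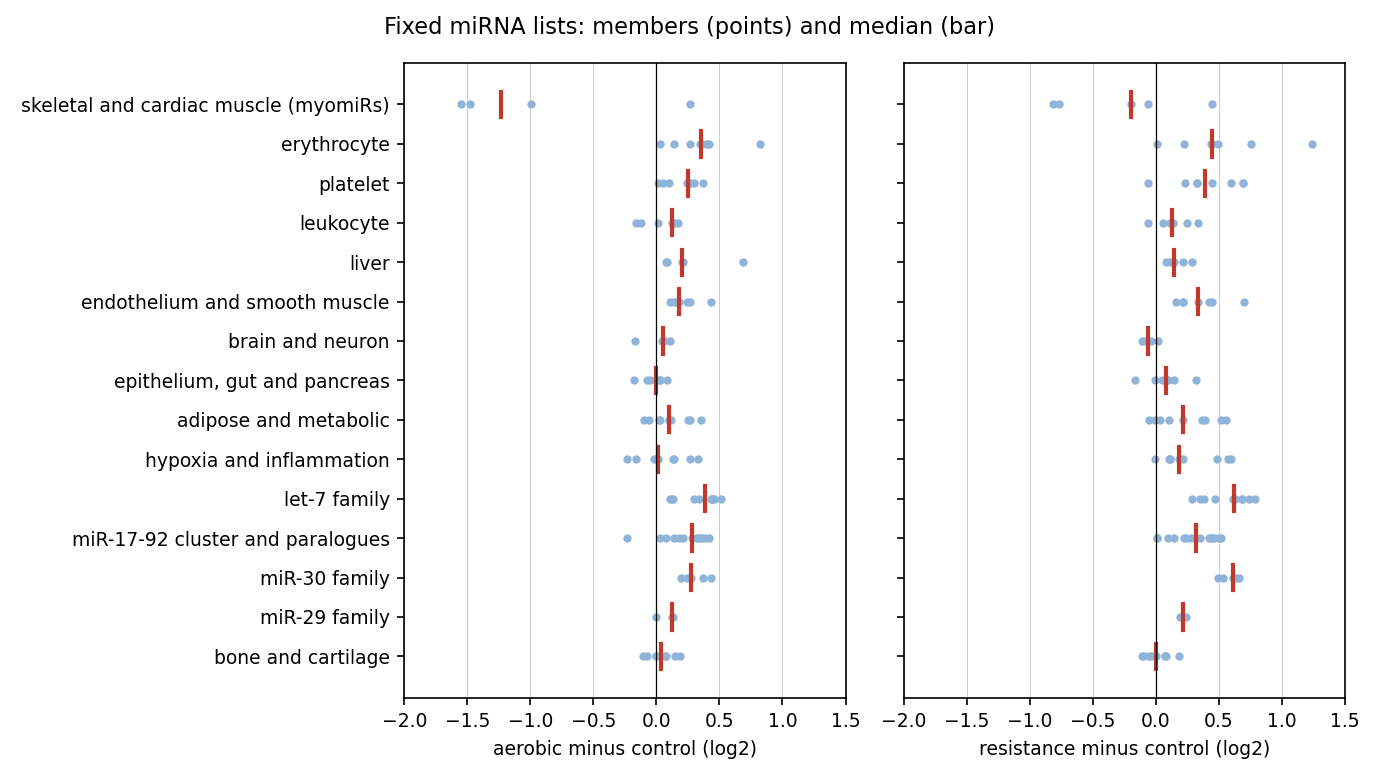
For each of the 15 fixed lists (rows), points are the compared members and the red bar is their median, as aerobic minus control (left) and resistance minus control (right) in log2 normalized intensity, with 1 array per pool. The muscle list has the lowest medians, -1.24 and -0.20, and the let-7 family the highest, 0.38 and 0.62.

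Of 1336 miRNAs compared, 3 were at least 2-fold higher (miR-185-5p, miR-16-5p and miR-6989-5p) and 1 at least 2-fold lower (miR-6912-5p). The authors' table gave 15 higher and 24 lower, and blank subtraction 11 and 25, each including those 4. With scaling to the median miR-6989-5p fell short of 2-fold, at 0.99, and 2 were higher. Detected on 1 of the 2 arrays only were 36 miRNAs in resistance and 95 in control plasma. miR-590-5p, at raw intensity 155.5 in the resistance pool and at background in the others, was at least 2.06-fold higher, and miR-1901 was at least 1.96-fold lower. The next bounds were 1.12-fold for miR-101a-3p and 1.11-fold for miR-155-5p higher, and 1.19-fold for miR-6920-5p and 1.07-fold for miR-7006-3p lower. These lay within spot scatter.

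The exercise modes were then set against each other. Resistance plasma held more miR-185-5p (2.82-fold) and more epithelial miR-205-5p (2.12-fold) than aerobic plasma. Muscle miRNAs were also higher after resistance than after aerobic exercise: miR-1a-3p by 1.74-fold, miR-133a-3p by 1.72-fold and miR-133b-3p by 1.59-fold. Liver miR-122-5p was 1.38-fold lower. In the authors' table the folds of miR-185-5p, miR-205-5p and miR-1a-3p were 8.16, 3.07 and 6.13. The folds of miR-185-5p and miR-1a-3p rest on aerobic spots under the 10 SD threshold, at raw intensities of 116.9 and 104.1, and are not exact.

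In log2 terms miR-205-5p stood at 1.09, miR-1a-3p at 0.80, miR-133a-3p at 0.78 and miR-6989-5p at 0.68. On the lower side were miR-6993-5p at -0.52, miR-122-5p at -0.46, miR-1897-5p at -0.46, miR-483-3p, from an intron of the growth factor gene Igf2, at -0.44 and miR-7057-5p at -0.42, a fold of 1.34 that was 2.13 in the authors' table. The muscle list had a median of 0.72 with 4 of 4 probes higher, above every random list drawn from all miRNAs. It lay at percentile 99.97 of low-numbered lists. Its median was positive under all alternatives fixed beforehand, the lowest being 0.16. The let-7 list had a median of 0.26 with 10 of 10 probes higher, also positive throughout, though its lowest median was 0.01 without scaling.

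Medians of the other lists in this comparison were positive for platelet (0.19), leukocyte (0.12), endothelium and smooth muscle (0.20), epithelium (0.09), adipose (0.08), hypoxia and inflammation (0.22), miR-17-92 (0.09), miR-30 (0.29), erythrocyte (0.09) and miR-29 (0.12), and each of these turned negative without scaling between arrays. That setting shifted the median of all miRNAs by 0.20 for aerobic against control and by -0.19 for resistance against aerobic, so these medians hold only relative to the array as a whole. The liver list had a median of 0.00 and a mean of -0.08. The brain list stood at -0.09 and the bone and cartilage list at -0.01, and the sign of all 3 medians depended on the alternative.

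Of 1307 miRNAs compared, 2 were at least 2-fold higher (miR-185-5p and miR-205-5p) and 0 at least 2-fold lower. The authors' table gave 11 higher and 19 lower. At the 10 SD threshold 1 remained higher, since miR-185-5p was too dim on the aerobic array. Without scaling 1 remained as well, as miR-205-5p stood at 0.84. Of miRNAs detected on 1 array only, 65 were in the resistance and 57 in the aerobic pool, with miR-590-5p at least 2.02-fold higher and miR-1901 at least 2.18-fold lower after resistance exercise.

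**Figure D3:**
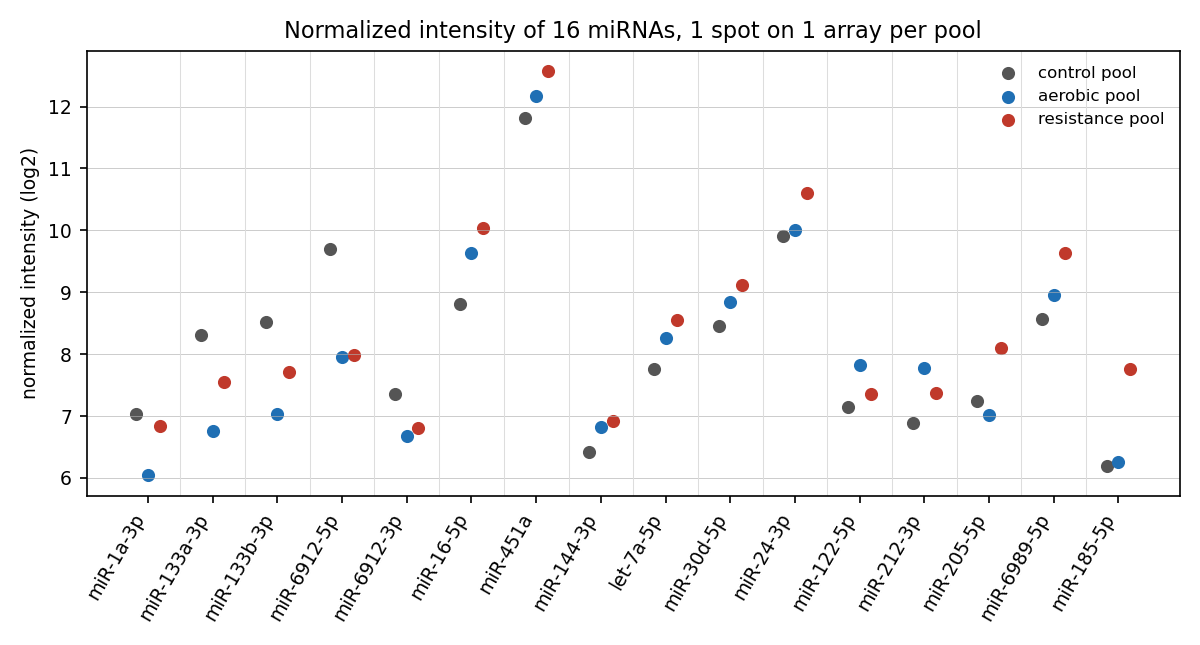
Normalized log2 intensity (y axis) of 16 miRNAs (x axis) on the control, aerobic and resistance arrays, 1 spot each and therefore without error bars. miR-133a-3p and miR-133b-3p are highest in the control and lowest in the aerobic pool, and miR-185-5p stands apart in the resistance pool alone. The 16 were picked for display after their values had been seen.

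Finally, the differences of both exercise pools from the caged pool were compared. miR-6912-5p was at least 2-fold lower in both. miR-16-5p, miR-6239 and miR-5100 were at least 1.5-fold higher in both, and miR-133a-3p, miR-133b-3p, miR-3093-5p and miR-6912-5p at least 1.5-fold lower in both. Unaltered groups sharing 1 control array would share 0.63 miRNAs at 2-fold lower in simulation, and 2.63 higher and 2.26 lower at 1.5-fold, and independent lists would share 0.00231, 0.102 and 0.0486. As many or more were shared in 49, 52 and 22 of the 100 simulations, in the same order. The simulated differences were about as wide as the observed ones, so these values do not show what wholly unaltered groups would share. The shared higher miRNAs depended on the processing: in the authors' table miR-5100 and miR-6239 were 1.28-fold and 1.46-fold higher after resistance exercise, and quantile normalization gave each of these the same value on both exercise arrays, although raw intensities were 9116 and 5913 for miR-5100. Across the 1296 miRNAs detected on all arrays, which are not independent replicates, the differences correlated with Pearson's r of 0.727 and Spearman's rho of 0.611. Unaltered groups sharing 1 control array gave r of 0.492 in simulation. The covariance was 0.0245 against a simulated 0.0144. The excess of the covariance was not seen under every setting: with blank subtraction the covariance was 0.0829 against a simulated 0.0824, and r 0.544 against 0.503. Without scaling the covariance of 0.0238 lay below a simulated 0.0313, while r, at 0.646, lay above a simulated 0.495. With scaling to the median the covariance was also 0.0238, above a simulated 0.0168. That scaling changes each array by a constant, so only the simulated value moved between these settings. The simulated covariance thus took in the shift between whole arrays, perhaps with blank subtraction too. Whether the excess depends on the setting cannot be read from blank subtraction or no scaling. With 1 control array no split of the controls was possible, and part or all of the excess may come from the shared control array. The differences from control had SDs of 0.171 (aerobic) and 0.197 (resistance), against 0.138 between the exercise pools.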

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

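The tests of single-spot defects, of processing and of muscle tissue RNA on the muscle miRNAs, the red cell test, the test against low-numbered miRNAs and 2 detection thresholds were chosen after the results they bear on had been seen.

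Some control spots passed the detection threshold more often than the blanks that set it. Spots without a probe passed in 78.7% of cases on the control array and 20.1% on the resistance array, against 5.69% and 6.14% of the blanks, but in 4.02% on the aerobic array against 8.93% of the blanks. Negative Control spots passed in 62.5% of cases on the control, 56.3% on the aerobic and 59.4% on the resistance array. S-Probe spots passed in 42.2%, 31.9% and 33.7% of cases and QC-Probe spots in 50%, 62.5% and 50%, in the same order. What S-Probe and QC-Probe spots carry is not described in the sources used here, so their passing need not be false detection.

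The control array also detected the most miRNAs, a pattern with technical explanations to weigh. With 1 common distance above background on all arrays, the control count lay below the higher exercise count by a difference of -122. That distance was the aerobic array's own, so the aerobic count of 1364 could not move. Control fell to 1242 and resistance to 1237, so control still lay slightly above resistance. With each array's own spots without a probe as reference the difference was -292. Both differences were set by the aerobic array, which was brighter before scaling. A threshold artefact would give such values, but the first rests on the array that its rule left unaltered. The larger number of miRNAs detected in control plasma may come from the narrow spread of its blanks and its brighter empty spots. A wider range of miRNAs in resting plasma was not tested separately.

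miR-133a-3p and miR-133b-3p were lower in both exercise pools, and miR-1a-3p beyond spot scatter in the aerobic pool alone. Chance defects of single spots are argued against in the aerobic pool, where the median of the muscle list lay at percentile 0.1 or lower of random lists under the settings planned, but not in the resistance pool, where it reached 44.3 without a detection filter, which adds probes detected on no array, and 2.43 with one, too high for 1 of 15 lists. The choice of background correction and scaling is argued against in the aerobic pool, as the list median stayed at -1.01 or lower under the other such settings, though it was -0.14 over all 8 probes without a detection filter. Muscle tissue RNA carried into the control pool during sampling could not be decided, because miR-206-3p lay near background and was not detected on the aerobic array, where its bound was 0.14 (log2) lower. An effect of exercise, a single unusual mouse in a pool of 3 and a difference between array hybridizations all stay open as untested, since each group had 1 array.

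The medians of the erythrocyte, let-7 and miR-30 lists lay above control in both exercise pools. Of 7 leukocyte probes 0 and 1 were higher by more than 2 SD of spot scatter, in the aerobic and resistance pools. Yet 5 and 6 of these 7 were higher at all, and the leukocyte list lay at percentiles 98.7 and 98.6 of all random lists. The offset compresses dim differences, so that limit is harder to pass for dim probes. A shift of all low-numbered miRNAs stays open: the joint median of the erythrocyte, let-7 and miR-30 lists lay at percentile 100 of random lists of other low-numbered miRNAs in both comparisons with control, but these lists were joined after their high values had been seen. Taken singly in the aerobic comparison, the let-7 list lay at percentile 100 and the erythrocyte list at 99.9. The liver list (100), the miR-17-92 group (99.98) and the adipose list (97.2) lay high as well. The lists of miR-30 (72.8), platelet (83.7), leukocyte (82.3) and endothelium (62.3) did not stand apart. In the resistance comparison the erythrocyte list lay at 97.1, below let-7 (100), miR-17-92 (99.8), adipose (99.4), epithelium (98.3) and miR-30 (97.3). High percentiles were thus not particular to the red cell and let-7 lists. Red cell RNA from lysis may still contribute and cannot be told apart from other sources, as miR-451a differed from the let-7 median by -0.0374 in the aerobic and 0.13 in the resistance pool, within the spot scatter that was set as the margin. An effect of exercise stays open as untested.

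miR-205-5p, a miRNA of skin and other epithelia, differed between the exercise pools by 1.09, being below control after aerobic and above it after resistance exercise. The difference was not tested, and its aerobic side lay within spot scatter and turned sign in other processing.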

How the results depend on the processing

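Detection above spots without a probe, a common detection distance, the 1.5-fold threshold and the authors' table with strict detection were alternatives chosen after seeing the data. No paired analysis was possible because each group had 1 array and no test was run. Leaving out a replicate was not applicable for the same reason. Each array held 1 group, so batch and group cannot be told apart. Many miRNAs lay close to background, where the handling of background bears on the fold. In the order aerobic against control, resistance against control and resistance against aerobic, the 2-fold counts were 0 higher and 3 lower, 3 and 1, and 2 and 0.

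Subtracting the blank mean gave 6 higher and 29 lower, 11 and 25, and 17 and 12. The authors' table gave 18 and 12, 15 and 24, and 11 and 19. With an offset of 0 the counts were 2 and 9, 8 and 2, and 5 and 0. A 1.5-fold threshold gave 6 and 9, 22 and 7, and 7 and 0. Simulated unaltered groups gave 7.98 and 7.89 for aerobic and 7.53 and 7.76 for resistance against control at that threshold. The counts against control were near these, except for the 22 higher in the resistance pool. The simulated differences were about as wide as the observed ones, however. Counts near the simulated ones thus do not show that the groups were unaltered. The authors' table with detection at 10 SD gave 2 and 6, 7 and 7, and 3 and 1. Without scaling, 4 were higher in aerobic against control and 1 in resistance against aerobic, where miR-205-5p was lost at 0.84. At 10 SD, 1 was higher in resistance against aerobic, and with no detection filter 1 was lower there. An offset of 0 does not pull dim folds towards 1 as the offset of 50 does. The cause of the wider counts under the table and blank subtraction was not tested. In simulated arrays blank subtraction shifted unaltered miRNAs of aerobic against control by a median of -0.34, and 4.88% of 1085 reached 2-fold, so its 29 lower miRNAs need not be uncompressed folds. All main 2-fold miRNAs of aerobic against control were kept under each alternative. In resistance against control miR-6989-5p was lost with scaling to the median, at 0.99.

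At 10 SD the detected counts were 808 in aerobic and 886 in resistance plasma. With detection above spots without a probe, 294 miRNAs were detected in only 1 of the aerobic and control pools and 192 in only 1 of the exercise pools. The correlation between both sets of differences from control, 0.727 as reported, was 0.544 with blank subtraction, 0.646 with median scaling, 75th percentile scaling or no scaling, 0.557 in the authors' table and 0.618 with an offset of 0. The cause was not tested.

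Without scaling between arrays, list medians for resistance against aerobic reversed to -0.0726 for platelet, -0.0382 for leukocyte, -0.123 for endothelium and smooth muscle, -0.0494 for epithelium, -0.0310 for adipose, -0.0350 for hypoxia and inflammation, -0.117 for miR-17-92 and -0.0609 for miR-30. The construction shows how: miRNA spots were brighter on the aerobic array, and without scaling the median of all miRNAs lay at -0.19. Spike-in spots differed by -0.07 and -0.10 in this comparison. Why the miRNA spots were brighter was not tested. The other settings reversed no list median that lay outside the central range of random lists, and no named difference of 2-fold or more changed sign under any setting. Smaller ones did: of 338 named differences, 69 changed sign without scaling, 27 with 75th percentile scaling, 15 with median scaling, 13 with blank subtraction and 11 in the authors' table. Blank subtraction shifted the median of all miRNAs by -0.14 and -0.16 for the aerobic and resistance pools against control.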

Other observations

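The correlation between hairpin arms was set out after both arms of miR-6912 had been seen to be lower but before its value was known, leaving out the 2 farthest miRNAs was chosen after it was known, and the miR-23, miR-24, miR-27 and miR-185-3p comparisons were chosen after their values had been seen.

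After scaling between arrays, the 3p arms of miR-23, miR-27 and miR-24 were higher in resistance plasma and differed less from control in aerobic plasma. They are encoded in paired clusters expressed in vessels and blood cells. Against control, miR-24-3p stood at 0.69 after resistance and 0.10 after aerobic exercise, miR-23a-3p at 0.57 and 0.14, miR-23b-3p at 0.54 and 0.07, miR-27b-3p at 0.56 and 0.25 and miR-27a-3p at 0.49 and 0.33. Among the 5p arms miR-23a-5p stood at 0.46 and 0.33, the dim miR-24-2-5p at 0.11 and 0.02, and miR-27b-5p was detected in the aerobic pool alone. The clusters are compact, with the start of Mir23a 154 bp from that of Mir27a. Probes of miR-23a-3p and miR-23b-3p are nearly identical, as are those of the miR-27 pair, so their values are not independent. The gap between the exercise pools was not tested, and for miR-23a-3p and miR-27a-3p it changed sign without scaling between arrays. Raw intensities on the aerobic and resistance arrays were close for the others as well. They were 1148 and 1160 for miR-23b-3p, 311 and 321 for miR-27b-3p, and 1278 and 1387 for miR-24-3p. The gap thus depends largely on the scaling between arrays.

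miR-185-5p was higher by 1.57 in resistance plasma, and miR-185-3p stood at -0.13. The low-numbered miRNAs, 627 of the probes, carried 10.1% of the signal above background in control, 11.2% in aerobic and 11.9% in resistance plasma, and probes numbered 1000 or higher carried 86.0%, 84.98% and 84.4%.

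A hypothesis was that differences from control follow shared precursors, so that both arms of a hairpin differ together. Across 401 hairpins in the aerobic comparison the arms correlated with r of 0.194, at percentile 99.96 of shuffled pairings, and across 396 in the resistance comparison with r of 0.198, at percentile 99.97. Hairpins are not independent replicates. Without the 2 farthest miRNAs, miR-3093-5p and miR-6912-5p, the aerobic r was 0.0917, at percentile 98.6 of shuffled pairings of that smaller set. In the resistance comparison r without miR-185-5p and miR-6912-5p was 0.165, at percentile 99.98. Both arms of a hairpin carry the same number, however, and low-numbered and high-numbered miRNAs had medians of opposite sign under the main setting. These were 0.0225 and -0.0096 in the aerobic comparison and 0.0297 and -0.0357 in the resistance comparison. Whether such a shift alone gives the correlation between arms was not tested. A shared precursor may explain a small part of the differences, but the shift by number stays open as well. Cross-hybridization between arms was not tested.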
